A study of Danio rerio with 12 samples.

How the data were processed

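RNA from whole zebrafish eyes was measured on 12 Affymetrix expression arrays, 1 biotin-labelled total RNA sample per array. The arrays form 4 groups of 3 pools each: eyes of fish heterozygous for a mutation in mmachc and eyes of mmachc mutants, at 7 and at 28 days post fertilization (dpf). The titles call the mutants homozygous, and the nature of the mutation is not given in the sources used here. Each array was placed in its group by its title, and its replicate number was taken from the same title. Nothing used here says how many fish entered a pool or whether pools came from separate clutches, so p-values measure only the spread between these pools. No scan date or slide is given in the sources used here, so no batch could be entered in a fit.

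The deposited values are log2 intensities per probe set that were made with Affymetrix Expression Console and RMA (background correction, quantile normalization and summary of the probes), per the submitters' processing notes, which give no versions. The labelling protocol names a human and mouse array type, while the probe table used here is that of a zebrafish platform, and the probe sets were named through that table. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. The 12 columns held 75212 probe sets with no missing value, ran from 1.55 to 13.3, and had medians between 5.64 and 5.70. No 2 arrays held identical values (0 identical pairs). The number of arrays limits the precision: the median standard error of a difference between 2 groups of 3 was 0.08 on the log2 scale.

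Of the probe sets, 20806 had 1 gene symbol, 855 had several and 53551 had none. For 20323 of those with 1 symbol the Entrez identifier was found in the RefSeq gene table of assembly GRCz12tu, which was used for names only. Only probe sets with 1 symbol entered the gene tests, which left 19260 genes. For the 1365 genes with several probe sets, the probe set with the highest mean over all 12 arrays stood for the gene. A gene was tested if it lay above the 33rd percentile of the named probe sets of the array on at least 3 of 12 arrays, which gave 14002 genes and left 5258 untested. The single probe set of mmachc also lists hspa8, so it was kept out of the tests of genes and is reported as a joint value.

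Differences were fitted with limma 3.58.1 in R 4.3.3 on the log2 values (lmFit with 1 mean per group, contrasts, eBayes with a trend of the variance on the mean level; 8 residual degrees of freedom). All 12 arrays entered a single fit, so that the groups shared an estimate of the spread. The contrasts were mutant minus heterozygous at 7 dpf, the same at 28 dpf, the difference between these differences (interaction), and 28 minus 7 dpf in heterozygous and in mutant eyes. Adjusted p-values are Benjamini-Hochberg values over the 14002 genes, and a gene rose or fell where its adjusted p lay under 0.05.

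A set of 36 gene lists was written before the data were examined. They cover the eye's tissues and cell types, other cell types that an eye sample could hold, the cobalamin pathway and metabolism next to it, and stress, immune, growth and clock genes. Of 1567 list entries 1376 matched a gene on the array, by symbol or by a synonym that leads to a single gene, and 191 did not. Each list was tested against the other genes with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. The counts of members that rose or fell are given with the adjustment over all genes and, in those words, adjusted over the list alone. Camera with a correlation estimated from these arrays and limma's fry were run as alternatives.

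The genes named in the text follow a rule written before the data were examined. For each genotype comparison it takes the 10 largest rises and 10 largest falls among genes past the threshold whose 3 mutant arrays all lay on the same side of the 3 heterozygous arrays, and for the interaction and the age comparison the 5 largest each way. From each list it takes up to 4 members past the threshold with the largest differences, or the 2 brightest members if none passed. Clone names were passed over: 1 among the rises and 3 among the falls at 7 dpf, the same numbers at 28 dpf, and 0 and 1 for the interaction.

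The fit was tested on simulated values drawn with the means and spread of these genes, in which 200 genes were shifted by 0.5 or 1 and the 40 members of a list by 0.3 on the log2 scale. At 7 dpf it recovered 85% of the genes shifted by 0.5 and 99% of those shifted by 1 on the log2 scale, and 2.91% of all calls, those among the list's members included, were false. At 28 dpf it recovered 82% and 100%, with 3.81% false, and for the interaction 57% and 92%, with 5.45% false. The real comparisons called far more genes (1743, 8513 and 6610), and the share of changed genes sets the Benjamini-Hochberg cut. These figures therefore need not hold for the real comparisons. For each comparison camera called the shifted list of 10 simulated lists and 0 of the others. The genes were drawn independently of each other, while members of the real lists can vary together. The simulation therefore does not show how often camera calls a real list by chance.

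The alternatives fixed beforehand were no filter, a filter at the median, another quantile normalization, centring of each array on the median of its named probe sets, cyclic loess between arrays, the mean over a gene's probe sets, all probe sets taken separately, a robust fit without the trend, array weights, fits of only the 6 arrays compared, the replicate number as a block, a minimum of 2-fold, the other gene set tests, and leaving out each array in turn. Added afterwards was taking off each array's trend with the mean level, by loess over the genes tested. Named probe sets were dimmer in mutant than in heterozygous eyes at 28 dpf, so that this centring adds 0.20 to every difference at 28 dpf, 0.17 to every interaction, 0.13 to every age difference in mutant eyes and 0.03 to every difference at 7 dpf, on the log2 scale. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.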

Results

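The arrays measured transcript levels in whole eyes of zebrafish heterozygous for a mutation in mmachc and of mmachc mutants, at 7 and at 28 dpf, with 3 pools in each of the 4 groups. The mmachc product processes cobalamin after its uptake into the cell, and loss of the human gene causes a combined disorder of methylmalonic acid and homocysteine. Within a group, the values of 2 arrays correlated over genes at 0.989 to 0.994. The probe set of mmachc also lists hspa8, so no level can be given to mmachc itself. The joint probe set measured 7.46 ± 0.03 in heterozygous and 7.37 ± 0.13 in mutant eyes at 7 dpf, and 7.31 ± 0.10 and 7.50 ± 0.09 at 28 dpf (log2, mean ± SD, n = 3). The differences of -0.10 and 0.19 (SE 0.08 each) did not pass limma's test, here fitted and adjusted over all 75212 probe sets (adjusted p = 0.735 and 0.132). That adjustment leaves a small difference at 28 dpf possible, and the probe set does not check the genotype labels.

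The comparison at 7 dpf asked which transcripts differed between the genotypes in larval eyes. Large rises were seen in nr1d4b and nr1d4a, which encode clock repressors of the Rev-erb family. Their levels were higher in mutant eyes by 3.49 ± 0.13 and 2.61 ± 0.11 on the log2 scale (difference ± SE, n = 3 against 3, limma adjusted p = 1.3e-10 and 3.9e-10). The activin antagonist fsta rose by 2.47 ± 0.11 (adjusted p = 3.9e-10) and the red cone opsin opn1lw1 by 1.71 ± 0.07 (adjusted p = 2.1e-10). Falls were seen in ankrd33ab, at -1.72 ± 0.22 (adjusted p = 7.2e-05), the clock gene per1b, at -1.53 ± 0.25 (adjusted p = 0.00062), and the kinase gene camkk1b, at -1.45 ± 0.13 (adjusted p = 2.5e-06). Other large rises were in fam131aa (1.82), the clock activator bmal2 (1.75), spsb3b (1.64), fbxl3l (1.53), guca1aa (1.47) and dtx4a (1.47). Other large falls were in pde5aa (-1.20), per3 (-1.19), the photolyase family gene cry-dash (-1.18), ncaldb (-1.16), the glutamate transporter gene slc1a8b (-1.16), guca1c (-1.11) and the complexin gene cplx4b (-1.07). Levels of fsta in heterozygous eyes (5.75), of cplx4b in both genotypes (6.11 and 5.04) and of hspb6, named below, in mutant eyes (5.42) lay below the 33rd percentile of their arrays. Signal over background was not measured, so the size of a difference to such a dim level is not exact. By the rule that chose these 20 genes, the 3 mutant arrays lay on the same side of the 3 heterozygous arrays in each.

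**Figure D1:**
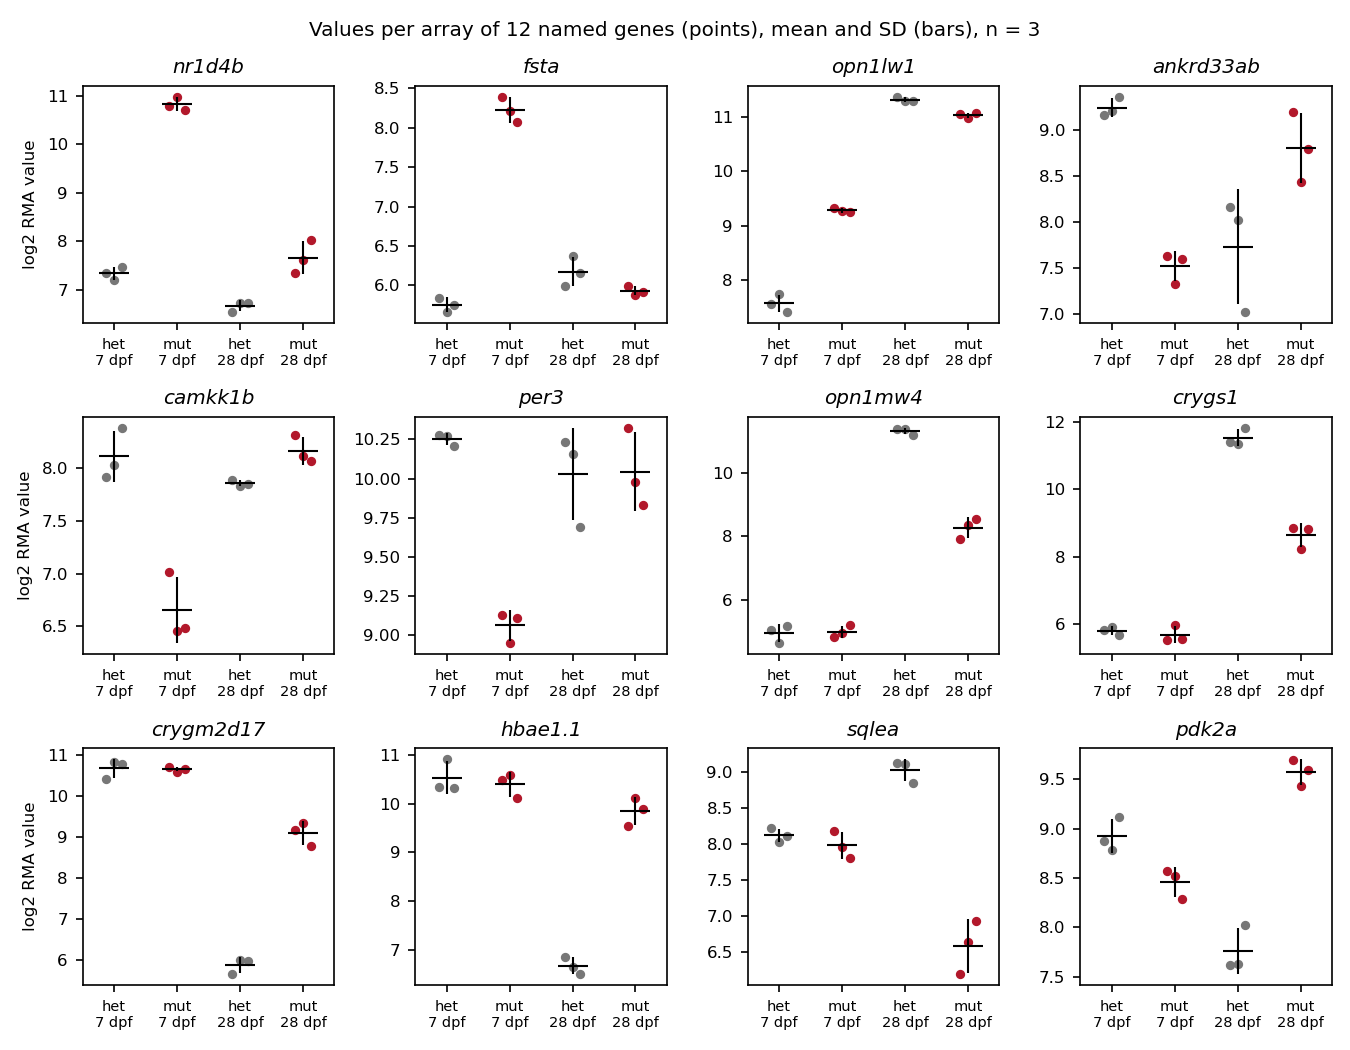
Values per array (points) with the mean and SD of the 3 pools (bars) for 12 named genes, on a log2 scale, in heterozygous (grey) and mutant (red) eyes at 7 and 28 dpf. At 7 dpf nr1d4b stood at 7.34 in heterozygous and 10.83 in mutant eyes, and at 28 dpf opn1mw4 stood at 11.33 and 8.28.

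Circadian clock genes were the list with the most calls at 7 dpf: of 42 members 8 rose and 18 fell (12 rose and 21 fell adjusted over the list alone). These 61.9% compare with 12.4% of all genes tested. Because the members moved both ways, camera, which tests a shift in a single direction, did not call the list (median -0.19, adjusted p = 0.401; 0.745 with an estimated correlation). The visual cycle and retinoid genes fell, 11 of 23 members with none rising (15 adjusted over the list alone). Among them were rdh5 (-0.55), rgra (-0.48), rpe65a (-0.46), the isomerase of the retinal pigment epithelium, and rlbp1b (-0.45). The list's median was -0.24 (camera adjusted p = 5.0e-06; adjusted p = 0.328 with an estimated correlation). Melanin pigment genes, which the same epithelium expresses, had 3 of 19 members that fell, slc45a2 (-0.36) and tspan36 (-0.37) among them, and 12 adjusted over the list alone (median -0.21, adjusted p = 0.00128; adjusted p = 0.702 with an estimated correlation).

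**Figure D2:**
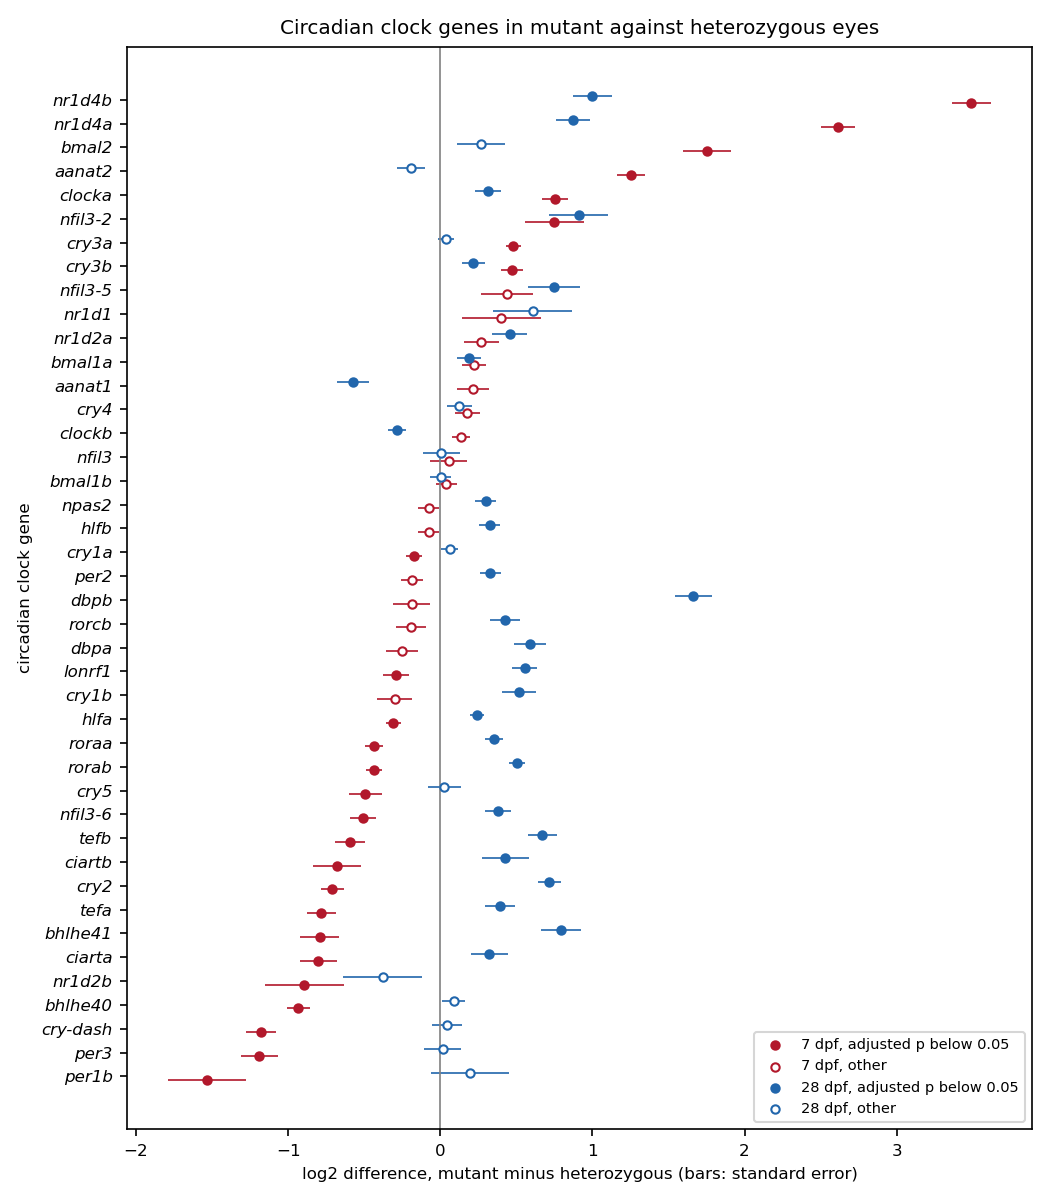
Difference between mutant and heterozygous eyes (log2, x axis) for each of the 42 circadian clock genes tested, at 7 dpf (red) and 28 dpf (blue), with standard errors as bars and filled points for an adjusted p below 0.05. At 7 dpf 8 members rose and 18 fell, and at 28 dpf 26 rose and 2 fell.

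Of 41 glycolysis genes 14 fell and 1 rose (20 and 1 adjusted over the list alone), with falls in the glucose transporter gene slc2a1a (-0.84), pdk2b (-0.54) and the hexokinase gene hk1 (-0.45). The median was -0.16 (camera adjusted p = 6.5e-06; adjusted p = 0.519 with an estimated correlation). Of 40 cobalamin, folate and methionine cycle genes 10 fell and 0 rose, by either adjustment, including adjusted over the list alone. The S-adenosylmethionine synthetase genes mat2ab (-1.04) and mat1a (-0.56) and the glycine methyltransferase gene gnmt (-0.64) were among them (median -0.13, adjusted p = 0.000545; adjusted p = 0.519 with an estimated correlation). Heat shock genes had 9 of 33 members that fell, both over all genes and adjusted over the list alone, such as hspb6 (-0.82) and hsf2 (-0.68; median -0.14, adjusted p = 0.000602; adjusted p = 0.689 with an estimated correlation). Amino acid and endoplasmic reticulum stress genes had 12 of 61 that fell and 2 that rose (20 and 4 adjusted over the list alone), with nars1 at -0.52 and cdkn1a at 1.06 (median -0.14, adjusted p = 0.00328; adjusted p = 0.702 with an estimated correlation). Antioxidant and glutathione genes had 4 of 37 that fell by either adjustment, over all genes and adjusted over the list alone, with pgd at -0.58 (median -0.13, adjusted p = 0.0183; adjusted p = 0.703 with an estimated correlation). That call was lost without replicate 3 of the mutant eyes at 7 dpf (adjusted p = 0.0673).

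Of 23 Muller glia genes 7 fell (9 adjusted over the list alone), led by the glutamate transporter gene slc1a2a (-1.05) and slc6a13 (-0.61; median -0.15, adjusted p = 0.00733; adjusted p = 0.519 with an estimated correlation). Corneal and skin epithelium genes had 5 of 31 that fell (7 adjusted over the list alone), krt94 (-0.39) and krt8 (-0.36) among them (median -0.21, adjusted p = 0.00315; adjusted p = 0.703 with an estimated correlation). Cytosolic ribosomal protein genes and skeletal muscle genes shifted up, though only 2 of 65 and 0 of 37 members rose, and 0 of either adjusted over the list alone. Their medians were 0.05 and 0.12 (adjusted p = 0.00315 and 0.0154; both adjusted p = 0.745 with an estimated correlation). The shift of the skeletal muscle genes was lost without replicate 3 of the heterozygous eyes (adjusted p = 0.227) or of the mutant eyes (adjusted p = 0.0849) at 7 dpf.

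Photoreceptor lists and the lists after them were not called by camera at 7 dpf, and members of the photoreceptor lists moved both ways. Of 35 cone photoreceptor genes 2 rose and 11 fell (4 and 12 adjusted over the list alone), with opn1lw1 up and guca1c, guca1d (-1.01) and the opsin kinase gene grk7a (-0.83) down. Rod photoreceptor genes had 4 of 23 in each direction (4 rose and 6 fell adjusted over the list alone). Outer segment and cilium genes had 4 of 30 that rose, such as rd3 (0.76), and 7 that fell, such as pdcb (-0.80; 5 and 9 adjusted over the list alone). Synapse genes had 5 of 48 that rose and 10 that fell (7 and 14 adjusted over the list alone), with cacna2d4a at 0.68 and cplx4b at -1.07. Bipolar cell genes had 1 of 20 that rose and 5 that fell (1 and 6 adjusted over the list alone), cabp5b at -0.90 among them. Reactive Muller glia genes had 4 of 33 that fell (8 adjusted over the list alone), rx1 (-0.67) among them. No member of the lens list (53 genes) or the myelin list (13 genes) passed, and of the brightest lens genes cryba2a differed by 0.01 ± 0.04 and cryba4 by 0.04 ± 0.04. In each of the other 16 lists between 1 and 5 members passed. Of 80 oxidative phosphorylation genes 5 fell, of 49 cell cycle genes 1 rose and 2 fell, of 51 matrix genes 2 rose and 1 fell, and of 18 p53 and apoptosis genes 2 rose. Adjusted over the list alone these were 4 falls, 1 fall, none, and 3 rises with 1 fall. Of 23 cholesterol synthesis genes 1 rose and 2 fell, and of 24 creatine and phosphatidylcholine genes and of 23 vascular endothelium genes 1 rose and 3 fell, with equal counts adjusted over the list alone. Branched chain catabolism, DNA methylation, neutrophil, erythrocyte, macrophage, horizontal cell, amacrine cell, retinal ganglion cell and interferon genes had at most 2 calls each by either adjustment, over all genes and adjusted over the list alone.

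In all, 567 genes rose and 1176 fell at 7 dpf, 1743 of 14002. Of them 27 rose and 21 fell at least 2-fold. The 3 mutant arrays did not overlap the 3 heterozygous arrays for 30.4% of the genes, against 10% by chance. The median of all 14002 differences was -0.03. The 11 lists called kept the sign of their median after every rescaling of the arrays, and 0 of them passed with an estimated correlation (lowest adjusted p = 0.328). Falls made up 67.5% of the calls, 57.2% after centring each array on its named probe sets and 53.6% with all probe sets taken separately.

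At 28 dpf the same comparison was made in juvenile eyes, and cholesterol synthesis genes were among the large falls. The squalene epoxidase gene sqlea was lower in mutant eyes by -2.45 ± 0.14 on the log2 scale (difference ± SE, n = 3 against 3, limma adjusted p = 3.7e-09). The lanosterol synthase gene lss was lower by -2.22 ± 0.11 (adjusted p = 1.3e-09), hsd17b7 by -2.16 ± 0.08 (adjusted p = 4.0e-11) and sc5d by -2.08 ± 0.10 (adjusted p = 9.5e-10). The fatty acid desaturase gene fads2 fell by 2.1 and STARD5, of a family of lipid transfer proteins, by 1.88. The green cone opsin opn1mw4 fell by 3.05 ± 0.15 (adjusted p = 1.3e-09), the lens crystallins crygs1 by 2.89 ± 0.16 (adjusted p = 2.3e-09) and crybb3 by 2.48 ± 0.08 (adjusted p = 1.4e-11), and the small heat shock gene hspb6 by 1.96. Rises were seen in the crystallins crygm2d17 (3.21 ± 0.13, adjusted p = 1.3e-10) and crygm2d16 (2.45 ± 0.20, adjusted p = 6.2e-08) and the haemoglobin gene hbae1.1 (3.19 ± 0.16, adjusted p = 1.5e-09). Rises in other genes were those of igf2bp1 (1.95), the pyruvate dehydrogenase kinase gene pdk2a (1.82), the carnitine palmitoyltransferase gene cpt1ab (1.76), cbx7a (1.74), the clock output gene dbpb (1.66), znf395a (1.54) and the vitamin D receptor gene vdrb (1.5). Crystallins, opsins and haemoglobins have close paralogs whose transcripts may share probes, so values of single members are uncertain. Dim levels, below the 33rd percentile of the arrays, make the sizes and their order inexact for crygm2d17 and crygm2d16 (5.88 and 3.39 in heterozygous eyes), cbx7a (6.16), lss (4.97 in mutant eyes) and hspb6 (5.77). Of the genes named below for 28 dpf this also holds for ndufa7, ogna, cdkn1a, slc6a5, fgf21, mmadhcb, cldnk and hbae3. The 3 mutant arrays lay on the same side of the 3 heterozygous arrays in all 20 genes, as the rule that chose them requires.

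Of 23 cholesterol synthesis genes 19 fell and 1 rose, both over all genes and adjusted over the list alone (median -0.91, camera adjusted p = 4.7e-06; adjusted p = 0.290 with an estimated correlation). Oxidative phosphorylation genes fell in 69 of 80 cases and rose in 2 (70 and 2 adjusted over the list alone), led by ndufa4b (-1.27), ndufa7 (-1.0) and cox7a2a (-0.91; median -0.42, adjusted p = 9.65e-08; adjusted p = 0.359 with an estimated correlation). Branched chain amino acid and propionate catabolism genes, whose pathway ends in a cobalamin-dependent step, had 22 of 31 that fell and 2 that rose by either adjustment, over all genes and adjusted over the list alone. Among them were suclg2 (-0.82), mccc1 (-0.76) and bckdhb (-0.64; median -0.31, adjusted p = 0.00613; adjusted p = 0.529 with an estimated correlation). Extracellular matrix, sclera and cartilage genes had 35 of 51 that fell and 1 that rose (36 and 1 adjusted over the list alone), with the collagen genes col10a1a (-1.80), col6a2 (-1.68) and col6a1 (-1.47) and the proteoglycan gene ogna (-1.43; median -0.53, adjusted p = 2.9e-05; adjusted p = 0.458 with an estimated correlation). Cell cycle genes had 36 of 49 that fell and 1 that rose (39 and 1 adjusted over the list alone), with ccna2 (-1.06), tyms (-0.84) and cdk1 (-0.80; median -0.47, adjusted p = 0.000105; adjusted p = 0.723 with an estimated correlation). After centring each array on its named probe sets these falls were fewer: 15 of 23 cholesterol, 45 of 80 oxidative phosphorylation, 14 of 31 branched chain, 28 of 51 matrix and 27 of 49 cell cycle genes.

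**Figure D3:**
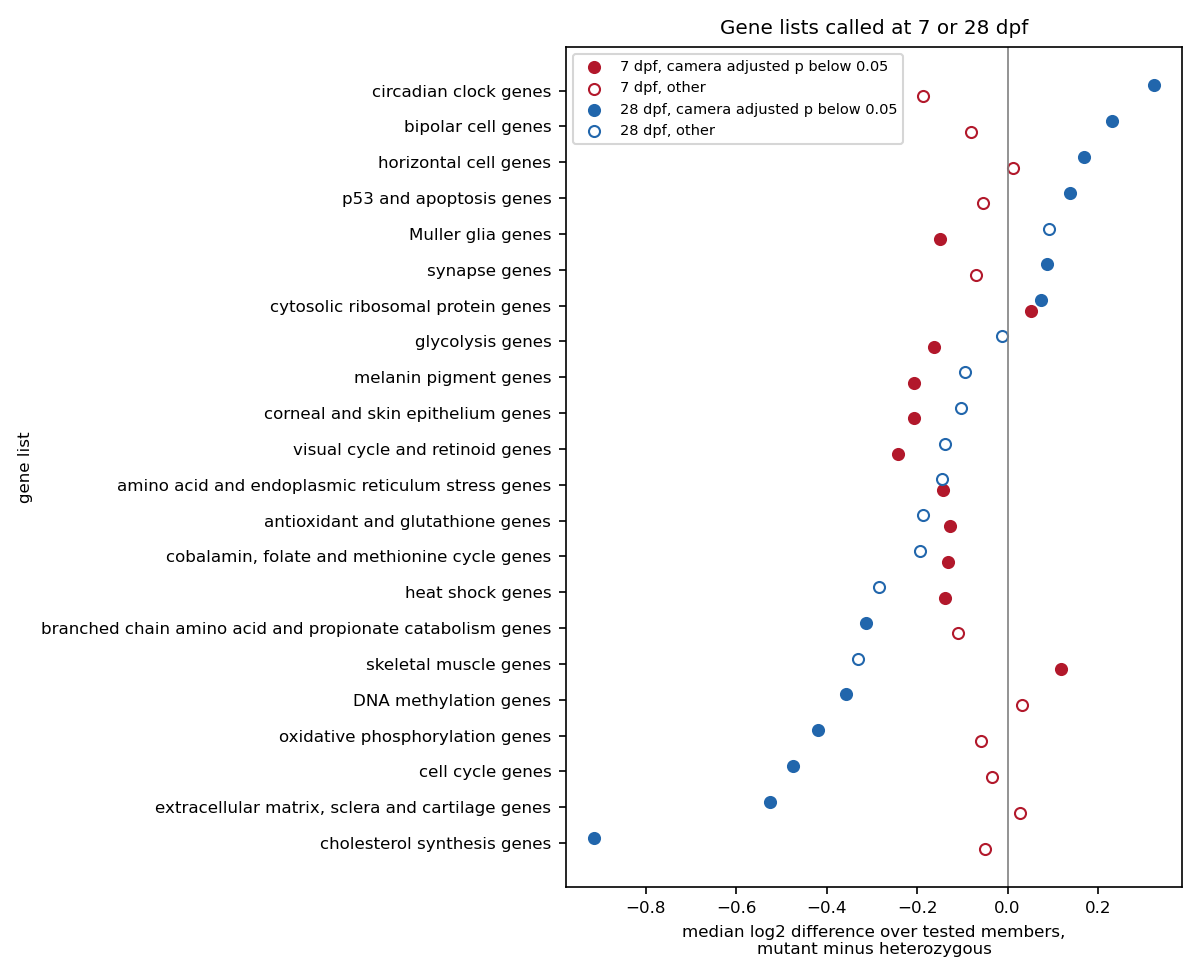
Median difference between mutant and heterozygous eyes (log2, x axis) of the gene lists that camera called at 7 dpf (red) or 28 dpf (blue), with open points where the adjusted p was 0.05 or more. Cholesterol synthesis genes had the lowest median at 28 dpf, -0.91, and circadian clock genes the highest, 0.32.

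Clock genes now rose in 26 of 42 cases and fell in 2 (27 and 2 adjusted over the list alone), with dbpb, nr1d4b (1.0), nfil3-2 (0.91) and nr1d4a (0.87) leading (median 0.32, adjusted p = 9.6e-07; adjusted p = 0.161 with an estimated correlation). Between pools at 28 dpf, the median SD of the clock genes was 0.17 in heterozygous and 0.16 in mutant eyes against 0.08 and 0.09 over all genes, while at 7 dpf it was 0.07 and 0.08, against 0.07 and 0.09. At 28 dpf levels of dbpb, per1b, per3 and nr1d4a ran in the order of the replicate number in both genotypes. Those of nr1d4b and bmal2 did not do so in both. The fit shares its estimate of the spread over the 4 groups, so it may understate the spread of clock genes at 28 dpf. Bipolar cell genes had 14 of 20 that rose and 2 that fell by either adjustment, over all genes and adjusted over the list alone, with the glutamate receptor gene grm6b (0.74), nyx (0.73) and samsn1a (0.66) up and fezf2 (-0.60) down (median 0.23, adjusted p = 0.000276; adjusted p = 0.264 with an estimated correlation). Synapse genes had 22 of 48 that rose and 10 that fell by either adjustment, including adjusted over the list alone, syt5b (0.77) and cacna1fb (0.64) up and cplx4b (-1.22) down (median 0.09, adjusted p = 0.00613; adjusted p = 0.290 with an estimated correlation). Of 18 p53 and apoptosis genes 8 rose and 1 fell (7 and 1 adjusted over the list alone). The p53 targets bbc3 (1.22), sesn1 (0.89) and cdkn1a (0.63) rose (median 0.14, adjusted p = 0.00619; adjusted p = 0.274 with an estimated correlation). Ribosomal protein genes had 16 of 65 that rose and 3 that fell (12 and 3 adjusted over the list alone), rps27.1 at 0.51 and rps8b at -0.48 (median 0.07, adjusted p = 0.00453; adjusted p = 0.708 with an estimated correlation). These counts depend on the scaling: after centring 34 clock genes rose and 1 fell, 17 and 1 bipolar cell, 32 and 3 synapse, 12 and 0 p53 and 51 and 1 ribosomal protein genes.

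Horizontal cell genes had 8 of 16 that rose and 2 that fell by either adjustment, over all genes and adjusted over the list alone, with onecutl (0.80) and onecut3a (0.73) up and gja9a (-0.70) down (median 0.17, adjusted p = 0.0383; adjusted p = 0.410 with an estimated correlation). The call was lost with no filter (adjusted p = 0.0752), with the mean over probe sets (0.0695), without replicate 3 of the heterozygous eyes (0.0609) and without replicate 2 of the mutant eyes (0.0576) at 28 dpf. DNA methylation genes had 11 of 19 that fell and 2 that rose (13 and 2 adjusted over the list alone), with the methyltransferase genes dnmt3aa (-1.12) and dnmt3ab (-0.83) and mbd3b (-0.84; median -0.36, adjusted p = 0.0455; adjusted p = 0.274 with an estimated correlation). Their call was lost without replicate 3 of the heterozygous eyes at 28 dpf (adjusted p = 0.0609) and with the replicate number as a block (camera adjusted p = 0.0524). After centring 10 horizontal cell genes rose and 1 fell, and 4 DNA methylation genes rose and 10 fell.

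Among the other retinal lists, which camera did not call, 14 of 23 rod photoreceptor genes fell and 3 rose, with rgs9bp (-0.74), gucy2f (-0.72) and pde6b (-0.72), and 9 fell and 4 rose after centring. Of 35 cone photoreceptor genes 13 rose, such as guca1g (1.02) and cngb3.2 (0.85), and 8 fell. Outer segment and cilium genes had 10 of 30 that rose and 9 that fell, reep6 (-1.13) and otx5 (0.77) among them. Muller glia genes had 8 of 23 that rose and 3 that fell, with the intermediate filament gene vim at 1.18. Reactive Muller glia genes had 10 of 33 that rose and 4 that fell, with mycb at 0.64 and fosl1a at -1.35. Retinal ganglion cell genes had 9 of 25 that rose and 5 that fell, with isl2a at 0.49 and stmn2a at -0.69. Amacrine cell genes had 6 of 21 in each direction, slc6a5 at -0.68 and calb2a at 0.57, and 11 rose and 1 fell after centring. The 5 lists between them moved upward too after centring: 20 cone genes rose and 1 fell, 18 and 7 outer segment, 15 and 2 Muller glia, 19 and 1 reactive Muller glia and 15 and 2 ganglion cell genes. Adjusted over the list alone, the counts in these 7 lists were equal to those over all genes.

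Camera called none of the remaining lists at 28 dpf. Among all 14002 genes tested 3051 rose and 5462 fell, against 5842 and 3284 after centring, so a surplus of falls is not by itself particular to a list. Heat shock genes had 17 of 33 that fell and 4 that rose, with hspb6, serpinh1a (-0.89) and fkbp4 (-0.76), and 12 fell and 10 rose after centring. For the lists that follow, centring evened out or turned the balance, as the second pair of counts shows. Of 40 cobalamin, folate and methionine cycle genes 5 rose and 23 fell, against 11 and 11 after centring, with gnmt at -1.72, mmadhcb, whose human counterpart acts with the mmachc product, at -0.81, and mthfd1l at -0.77. Amino acid and endoplasmic reticulum stress genes had 12 of 61 that rose and 29 that fell, against 20 and 15, with fgf21 at 1.01 and manf at -1.02. Antioxidant and glutathione genes had 2 of 37 that rose and 19 that fell, against 13 and 8, with msrb1b at -1.26. Visual cycle genes had 3 of 23 that rose and 11 that fell, against 9 and 5, rpe65a at -0.62 and rdh5 at -0.61 among them. Lens genes had 11 of 53 that rose and 16 that fell, against 28 and 9, and glycolysis genes 7 of 41 and 8, against 23 and 2. Skeletal muscle genes had 3 of 37 that rose and 16 that fell, against 9 and 5, with acta1b at -1.21 and mb at 0.89. Corneal and skin epithelium genes had 4 of 31 that rose and 11 that fell, against 14 and 9, with cyt1l at 1.38 and krt15 at -1.34. Creatine and phosphatidylcholine synthesis genes had 6 of 24 and 9, against 13 and 5, with ckba at -0.72. Melanin pigment genes had 4 of 19 and 5, against 7 and 2, with pmelb at -0.61.

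Vascular endothelium genes had 4 of 23 that rose and 12 that fell at 28 dpf, against 7 and 7 after centring, with flt4 at -0.77. Macrophage and microglia genes had 2 of 17 and 5, against 6 and 3, with cd74a at -1.35 and mpeg1.2 at 0.60. Neutrophil, complement and acute phase genes had 1 of 12 and 5, against 3 and 3, with c7a at -0.65. Interferon response genes had 3 of 15 and 7, against 4 and 4, with tap1 at -0.55. Myelin and oligodendrocyte genes had 2 of 13 and 5, against 5 and 4, with cldnk at -0.59. Erythrocyte genes had 3 of 13 and 7, against 4 and 4, with the embryonic haemoglobin genes hbae3 (1.46) and hbbe2 (1.37) and hbae1.1 up and urod (-0.86) down. Adjusted over the list alone, counts in these 17 lists moved by at most 1 gene.

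In all, 3051 genes rose and 5462 fell at 28 dpf, 8513 of 14002, and 67 rose and 286 fell at least 2-fold. The groups did not overlap for 64.4% of the genes, against 10% by chance. The 12 lists called kept the sign of their median after every rescaling, and 0 passed with an estimated correlation (lowest adjusted p = 0.161). The share of falls depends on the scaling: 64.2% of the calls as deposited, 61.4% after cyclic loess, 56.8% after another quantile normalization and 36% after centring each array on its named probe sets, which adds 0.20 to every difference.

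The interaction asked whether the genotype difference itself changed with age. Ankrd33ab was lower in mutant eyes at 7 dpf (9.24 ± 0.10 in heterozygous and 7.52 ± 0.17 in mutant eyes, mean ± SD, n = 3) and higher at 28 dpf (7.73 ± 0.62 and 8.80 ± 0.38), an interaction of 2.80 ± 0.32 (limma adjusted p = 5.4e-06). Fsta showed the opposite change, from 5.75 ± 0.09 and 8.22 ± 0.16 at 7 dpf to 6.18 ± 0.19 and 5.93 ± 0.06 at 28 dpf (interaction -2.71 ± 0.15, adjusted p = 1.1e-08). In opn1mw4, crygs1 and crybb3 the difference opened at 28 dpf, with interactions of -3.10 ± 0.22 (adjusted p = 8.6e-08), -2.77 ± 0.23 (adjusted p = 3.1e-07) and -2.59 ± 0.12 (adjusted p = 1.5e-09). It opened upward in hbae1.1 (3.32 ± 0.23, adjusted p = 8.6e-08), crygm2d17 (3.24) and crygm2d16 (2.64), while in pdk2a it turned from -0.47 to 1.82 (interaction 2.28). For the cartilage collagen gene col10a1a the interaction was -2.97 ± 0.54 (adjusted p = 0.00037), with wide spread between pools (SD 0.93 in heterozygous eyes at 7 dpf). At least 1 of the 4 group means was dim for fsta, opn1mw4, crygs1, crygm2d17, crygm2d16 and col10a1a, so the sizes of these interactions are not exact either. The red opsin opn1lw1, higher in mutant eyes at 7 dpf, stood at 11.31 ± 0.04 in heterozygous and 11.02 ± 0.05 in mutant eyes at 28 dpf.

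By camera 14 lists differed in their shift between the ages, and 0 passed with an estimated correlation (lowest adjusted p = 0.178). Matrix genes (median -0.59, adjusted p = 3.3e-06; adjusted p = 0.305 with an estimated correlation) and oxidative phosphorylation genes (-0.33, adjusted p = 1.1e-05; adjusted p = 0.353 with an estimated correlation) were lower in mutant eyes at 28 dpf relative to 7 dpf. So were cholesterol synthesis genes (-0.79, adjusted p = 1.4e-05; adjusted p = 0.30 with an estimated correlation) and cell cycle genes (-0.41, adjusted p = 0.000298; adjusted p = 0.668 with an estimated correlation). Clock genes (0.51, adjusted p = 9.0e-05) and bipolar cell genes (0.33, adjusted p = 7.4e-05) went up relative to 7 dpf (both adjusted p = 0.178 with an estimated correlation). Of 41 glycolysis genes 16 had a positive and 5 a negative interaction (16 and 5 adjusted over the list alone; median 0.19, adjusted p = 0.000332; adjusted p = 0.353 with an estimated correlation). Of 23 Muller glia genes 11 had a positive and 2 a negative interaction (12 and 2 adjusted over the list alone; median 0.25, adjusted p = 0.00201; adjusted p = 0.271 with an estimated correlation). After centring the counts were 27 and 3 for glycolysis and 14 and 1 for Muller glia genes. Synapse genes (0.08, adjusted p = 0.00284; adjusted p = 0.271 with an estimated correlation) and cone photoreceptor genes (0.13, adjusted p = 0.00284; adjusted p = 0.30 with an estimated correlation) shifted up. Reactive Muller glia genes (0.17, adjusted p = 0.00984; adjusted p = 0.353 with an estimated correlation) and p53 genes (0.25, adjusted p = 0.0314; adjusted p = 0.30 with an estimated correlation) did so too. DNA methylation genes shifted down (-0.31, adjusted p = 0.0133; adjusted p = 0.178 with an estimated correlation). The p53 genes lost their call without replicate 1 of the heterozygous eyes at 28 dpf (adjusted p = 0.0511). Rod photoreceptor genes shifted down (median -0.31, adjusted p = 0.0468; adjusted p = 0.714 with an estimated correlation). Their call was lost with the mean over probe sets (0.0563) and without replicate 2 (0.0833) or 3 (0.0503) of the heterozygous or 2 (0.0990) of the mutant eyes at 28 dpf. It was also lost without replicate 2 (0.0695) of the heterozygous or 1 (0.0661) or 2 (0.0773) of the mutant eyes at 7 dpf. The replicate number as a block ended the call too (camera adjusted p = 0.0591).

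In all, 2530 genes had a positive and 4080 a negative interaction, 6610 of 14002. Of the 1133 genes called at both ages, against 1059.7 for independent lists, 306 rose at both, 362 fell at both, 386 fell at 7 dpf and rose at 28 dpf, and 79 did the reverse. All 465 of opposite direction passed the test of the interaction, which calls of opposite sign at both ages ensure in a shared fit. Over genes, which are not independent replicates, the genotype differences at the 2 ages correlated at r = 0.0546. Negative values made up 61.7% of the interactions called and 35.3% after centring.

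The age comparison in heterozygous eyes asked how transcript levels changed with age in the control genotype. From 7 to 28 dpf the crystallins crygm6 and crygs1 and the green opsins opn1mw4 and opn1mw3 rose, as did crygm2a (5.63). The crystallins rose by 6.64 ± 0.15 and 5.71 ± 0.16 (log2, n = 3 against 3, limma adjusted p = 8.9e-15 and 1.5e-13) and the opsins by 6.39 ± 0.15 and 6.14 ± 0.14 (adjusted p = 2.2e-14 and 8.9e-15). At 7 dpf these 4 genes lay at 4.53, 5.81, 4.94 and 4.77, below the 33rd percentile of the arrays, so the sizes and their order are not exact. Falls were seen in crygm2d17 (-4.79), crygm2d16 (-4.41), hbae3 (-3.92), hbae1.1 (-3.87) and crygm2d6 (-3.76), of which all but hbae1.1 reached such dim levels. Rod photoreceptor genes rose in 21 of 23 cases and fell in 0 (22 and 0 adjusted over the list alone; median 0.90, camera adjusted p = 2.3e-17; adjusted p = 0.117 with an estimated correlation). Skeletal muscle genes rose in 30 of 37 cases (30 adjusted over the list alone; median 1.01, adjusted p = 2.5e-10; adjusted p = 0.309 with an estimated correlation). Matrix genes rose in 33 of 51 (33 adjusted over the list alone; median 0.61, adjusted p = 3.6e-11; adjusted p = 0.234 with an estimated correlation). Cell cycle genes fell in 45 of 49 cases (47 adjusted over the list alone; median -0.51, adjusted p = 1.2e-13; adjusted p = 0.309 with an estimated correlation). Clock genes fell in 26 of 42 (28 adjusted over the list alone; median -0.34, adjusted p = 7.9e-08; adjusted p = 0.0646 with an estimated correlation). The other lists called were the ribosomal (median -0.22) and melanin (-0.38) genes, which went down, and the lens (0.29), vascular (0.35), macrophage (0.33), neutrophil (0.36), myelin (0.13), interferon (0.47) and cholesterol (0.08) genes, which went up. With an estimated correlation none of them passed: the adjusted p was 0.309 for the ribosomal, melanin and lens genes, 0.0646 for vascular, 0.26 for macrophage, 0.323 for neutrophil and myelin, 0.234 for interferon and 0.597 for cholesterol genes. In all 2927 genes rose and 3094 fell with age in heterozygous eyes, and 3645 and 5303 in mutant eyes, where centring lowered the share of falls from 59.3% to 41.0%. The share of falls in heterozygous eyes was 51.4% as deposited, 59.4% after centring and 45.2% after cyclic loess. By camera 14 lists were called in heterozygous eyes, 10 of them up, and 0 passed with an estimated correlation (lowest adjusted p = 0.0646).

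**Figure D4:**
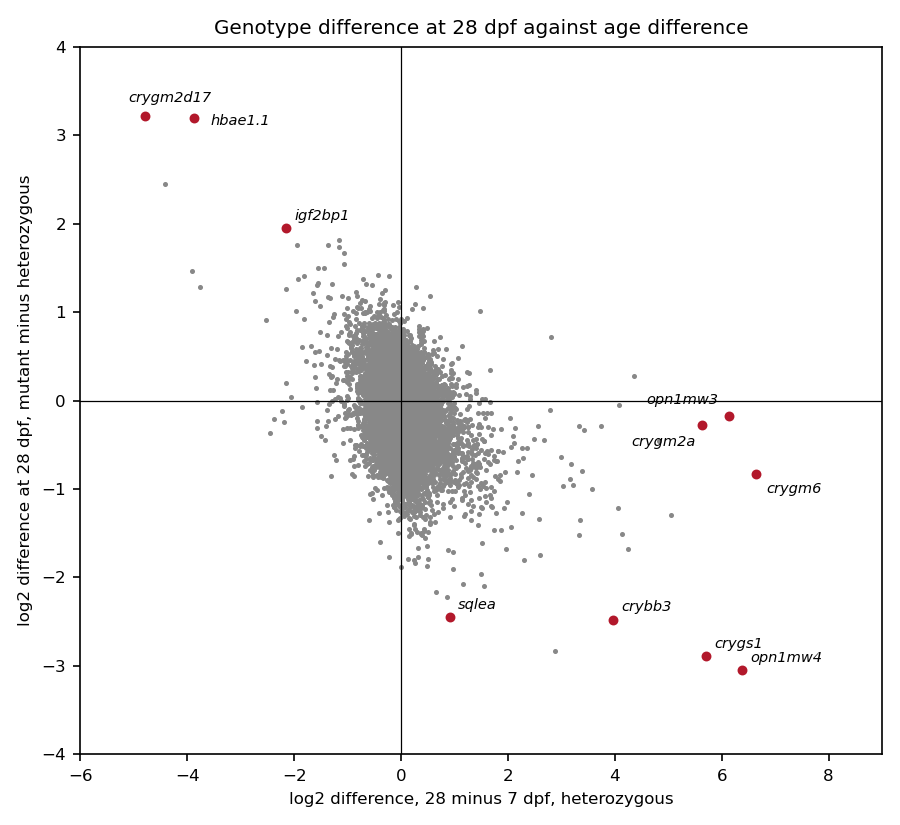
Each point is a gene: the change from 7 to 28 dpf in heterozygous eyes (log2, x axis) against the difference between mutant and heterozygous eyes at 28 dpf (log2, y axis), with 10 named genes in red. The points slope downward, so that opn1mw4, which rose by 6.39 with age, was lower in mutant eyes (-3.05) and crygm2d17, which fell by 4.79, was higher (3.21).

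Of the 2927 genes that rose with age in heterozygous eyes, 1564 were lower and 297 higher in mutant eyes at 28 dpf. Of the 3094 that fell, 1200 were higher and 797 lower. Independent lists would give 1141.8, 637.8, 674.2 and 1206.9. The heterozygous arrays at 28 dpf enter both differences, which alone makes them covary: the observed covariance over genes was -0.0638, and simulated groups without effects gave -0.00469. With the heterozygous arrays at 28 dpf divided so that no array was shared, the correlation over genes was between -0.345 and -0.297 in the 3 divisions.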

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

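The tests of clock phase, of a clock effect alike at both ages, of slower development for the cell cycle genes and of an intensity-dependent cause, for all 3 patterns, were chosen only after the result was seen, as were the counts of 2-fold calls by direction under each scaling.

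The genotype difference differed between the ages for 6610 genes and, by camera, for 14 lists, each by a test of the interaction; with an estimated correlation 0 lists passed (lowest adjusted p = 0.178). The median interactions (log2, 28 minus 7 dpf) were -0.79 over cholesterol synthesis genes, -0.59 over matrix genes, -0.41 over cell cycle genes, -0.33 over oxidative phosphorylation genes, -0.31 over rod photoreceptor genes and -0.31 over DNA methylation genes. They were 0.51 over circadian clock genes, 0.33 over bipolar cell genes, 0.25 over Muller glia genes, 0.25 over p53 and apoptosis genes, 0.19 over glycolysis genes, 0.17 over reactive Muller glia genes, 0.13 over cone photoreceptor genes and 0.084 over synapse genes.

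Of 46 genes named for the size of their difference in any comparison, 43 had an interaction, against 47.2% of all genes tested; picking genes by size, the interaction's included, raises that share by itself. Values above 2 were those of hbae1.1 (3.32), crygm2d17 (3.24), ankrd33ab (2.80), crygm2d16 (2.64), pdk2a (2.28) and cbx7a (2.03). Lower positive values were those of igf2bp1 (1.94), dbpb (1.85), camkk1b (1.76), crygm2d6 (1.75), znf395a (1.74), per1b (1.73), cpt1ab (1.73), vdrb (1.60), hbae3 (1.48), cry-dash (1.22), per3 (1.2), ncaldb (1.16), slc1a8b (1.07), pde5aa (1.02) and guca1c (0.74). Negative values below -2 were those of opn1mw4 (-3.10), col10a1a (-2.97), crygs1 (-2.77), fsta (-2.71), crybb3 (-2.59), nr1d4b (-2.49), lss (-2.43), sqlea (-2.31), hsd17b7 (-2.23) and sc5d (-2.15). The others were opn1lw1 (-1.99), fads2 (-1.90), STARD5 (-1.81), nr1d4a (-1.74), fam131aa (-1.54), bmal2 (-1.48), fbxl3l (-1.27), hspb6 (-1.15), dtx4a (-1.07), spsb3b (-1.0), crygm6 (-0.83) and guca1aa (-0.66). For 13 of the 43 at least 1 group mean lay below the 33rd percentile of its arrays, so the size and order of their interactions are not exact: opn1mw4, col10a1a, crygs1, fsta, lss, hspb6, crygm6, crygm2d17, crygm2d16, crygm2d6, hbae3, cbx7a and cry-dash. Of 287 other named list members, 205 had an interaction.

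Probe sets that were kept out of the gene tests also differed between the genotypes, with each probe set tested on its own. Of 18815 probe sets without a gene symbol 1144 passed at 7 dpf (710 rose, 434 fell) and 7346 at 28 dpf (3630 rose, 3716 fell). Of 521 probe sets with several symbols 28 passed at 7 dpf and 237 at 28 dpf.

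At 7 dpf 26 of 42 clock genes differed between the genotypes. An intensity-dependent difference between arrays is argued against by its small size: Spearman's rho of the difference with the level was -0.0596. Once each array's trend with the mean level was taken off (rho = -0.0123), 26 clock genes were still called. Taking off so small a trend could hardly have removed the calls, so that count adds little. Of 16 clock genes called at both ages, 31.2% had the same sign and 11 had opposite signs, so most of these differences changed direction. All 11 passed the test of the interaction, but calls of opposite sign at both ages ensure that, so it adds nothing. These signs cannot decide on a mutation effect on the clock that is alike at both ages. The same shift of phase can give opposite signs if the ages were collected at different times of day. The fit may also understate the spread of clock genes at the later age. A different clock phase at collection in the mutant and heterozygous fish may account for the pattern, but its test did not settle it: the 6 genes of the bmal, clock and npas2 arm had a median of 0.18 and the 12 of the per, nr1d, dbp and tef arm -0.22, which is 0.40 apart (2-sided exact permutation p = 0.307). Of these 12 genes 2 rose, nr1d4a and nr1d4b, and 5 fell, so a difference of arm medians may miss a shift of phase. Collection times are not given in the sources used here. An effect of genotype on the clock that depends on age stays open, untested, and an effect alike at both ages stays open too.

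Part of the genes that changed with age in heterozygous eyes differed in mutant eyes at 28 dpf in the direction of their 7 dpf level. Of 2927 that rose 1564 were lower and 297 higher in mutant eyes, and of 3094 that fell 1200 were higher and 797 lower. These counts take the direction only, so genes that went past their 7 dpf level, such as sqlea and hsd17b7, are among them. Noise of single heterozygous arrays at 28 dpf, which enter both differences, is argued against as the whole cause. With none shared the lowest of 3 correlations over genes was -0.345. An intensity-dependent difference is argued against too, since the highest was -0.295 once each array's level trend was taken off (rho of the genotype difference 0.132 before and 0.0216 after). A trait of all 3 heterozygous pools at 28 dpf still enters both differences and cannot be told apart from slower development here. Slower development of mutant eyes may account for part of the pattern, as the correlation it needs was there in all 3 divisions (highest -0.297). As the whole cause, slower development is argued against for cholesterol synthesis genes. Their median moved by 0.083 with age in heterozygous eyes (quartiles -0.12 and 0.56) and by -0.53 in mutant eyes (quartiles -1.07 and -0.28). For members that rose with age in heterozygous eyes, such as sqlea, it may account for part of the fall. For cell cycle genes a mere delay along the age course of heterozygous eyes is argued against, by a test chosen after their fall was seen. They fell with age and yet lay lower still in mutant eyes at 28 dpf (median -0.47, quartiles -0.65 and -0.27). Slower development that also lowers cell division is not tested by these values. A different makeup of cell types or a direct effect of the mutation stays open, untested.

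More genes fell than rose in mutant eyes at 28 dpf. An intensity-dependent difference between arrays stays open: after cyclic loess 61.4% of the calls were falls, but that correction left the trend with the level in place (rho = 0.132 before and 0.134 after), and taking the trend off also centres the differences. A single scaling factor per array cannot be told apart from a true surplus of falls: of the calls of at least 2-fold 81.0% fell as deposited and 44.3% after centring each array on its named probe sets. What keeps it open is that RMA had set the arrays alike over all probe sets, while probe sets without a symbol, unlike named ones, rose and fell about equally often.

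Other splits of the 12 arrays were tried for the interaction, 100 drawn of 200. Only 1, the real one, reached its 6610 genes, and the highest other gave 5995. So chance can be excluded against arrays with no genotype effect at either age, but not for the interaction alone. The highest other and 8 more that kept the genotypes at 28 dpf gave 4901 to 5995 genes, and all others at most 135, so the count rests mostly on the 28 dpf difference. Splits that keep those genotypes are too few for a share under 0.05. For the 14 lists chance could not be excluded, since 13 of 100 splits gave as many and the highest other gave 18. A comparison of 3 against 3 has 10 splits, too few for a share under 0.05. The real counts and the highest others were 1743 and 1 genes at 7 dpf, 8513 and 1 at 28 dpf, 6021 and 0 for age in heterozygous eyes, and 8948 and 0 in mutant eyes. For lists they were 11 and 13 at 7 dpf (2 of 10 splits gave as many) and 12 and 15 at 28 dpf (4 of 10).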

How the results depend on the processing

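The counts of 2-fold calls by direction and the counts of list members under each scaling were chosen only after the result was seen. Of 285 results for named genes 245 kept their call under every alternative run, 40 changed it under at least 1, and 0 reversed; no called list reversed. With all probe sets taken separately the counts were 15775 at 28 dpf, 11393 for the interaction, 10387 for age in heterozygous and 17150 in mutant eyes, since 33957 probe sets were then tested in place of 14002 genes. Array weights gave 2884 genes at 7 dpf; the cause was not tested. A minimum of 2-fold left 48 genes at 7 dpf, 353 at 28 dpf, 453 for the interaction, 382 for age in heterozygous and 539 in mutant eyes. Camera with an estimated correlation called 0 lists at 7 dpf, 0 at 28 dpf and 0 for the interaction, and fry, which asks another question, called 24 at 28 dpf. Without 1 array the counts ran from 1214 to 1811 at 7 dpf, 7692 to 8101 at 28 dpf, 5930 to 6696 for the interaction, 5031 to 5255 for age in heterozygous and 8207 to 8696 in mutant eyes, and the lists from 10 to 13, 10 to 16 and 13 to 15. The replicate number as a block gave 1962 genes and 11 lists at 7 dpf, 8697 and 11 at 28 dpf, 6796 and 13 for the interaction, 6033 for age in heterozygous and 8967 in mutant eyes; camera then did not call the DNA methylation genes at 28 dpf (adjusted p = 0.0524) nor the rod photoreceptor genes for the interaction (0.0591). Deviations of same-numbered arrays correlated at -0.0682, 0.0552 and 0.122 at 7 dpf and 0.139, 0.0882 and 0.0955 at 28 dpf. At 7 dpf 1 of 3 and at 28 dpf 3 of 3 arrays matched their own number best. The sources used here do not say what same-numbered pools share, so a pairing at 28 dpf is neither shown nor excluded. Another background correction, a slide or date block and any alternative for mmachc alone were not run. Signal over background was not measured, so dim genes were only filtered by rank.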

Other observations

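The gene families below were chosen only after the data were seen, by the stem of their symbols, 12 in all, as were the members named here. At 28 dpf 4 families of channel and receptor genes were called up in mutant eyes. Of 39 voltage-gated calcium channel genes 27 rose and 1 fell, such as cacna1ha (0.77) and cacna2d3a (0.65 on the log2 scale), with a median of 0.26 (camera adjusted p = 6.9e-08; adjusted p = 0.0458 with an estimated correlation). Of 87 potassium channel genes 38 rose and 13 fell, with kcnh6b (0.92) and kcna3a (0.82) up (median 0.20, adjusted p = 1.8e-05; adjusted p = 0.0226 with an estimated correlation). Glutamate receptor genes had 18 of 35 that rose and 2 that fell, grin2cb at 1.12 among them (median 0.18, adjusted p = 2.3e-05; adjusted p = 0.215 with an estimated correlation), and GABA receptor genes 10 of 20 and 2, gabrr2a at 0.73 (median 0.17, adjusted p = 0.00148; adjusted p = 0.0504 with an estimated correlation). These 4 medians were positive under each scaling, but their size and the counts depend on it: after centring each array on its named probe sets 36 calcium channel genes rose and 0 fell, 61 and 9 potassium channel, 29 and 0 glutamate receptor and 17 and 0 GABA receptor genes, with medians of 0.45, 0.40, 0.38 and 0.37.

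Another 5 families were called down at 28 dpf, and 0 of these passed with an estimated correlation. Of 61 mitochondrial ribosomal protein genes 42 fell and 2 rose, mrpl27 (-1.27) and mrps18a (-1.07) among them (median -0.53, adjusted p = 2.9e-05; adjusted p = 0.377 with an estimated correlation). Proteasome subunit genes had 36 of 40 that fell and 1 that rose, with psmd5 at -1.0 and psmc5 at -0.85 (median -0.45, adjusted p = 1.8e-05; adjusted p = 0.377 with an estimated correlation). After centring each array on its named probe sets 33 and 27 fell. Mitochondrial import, splicing factor and V-type ATPase genes were called down too (adjusted p = 0.0323, 0.00568 and 0.0484; adjusted p = 0.481, 0.377 and 0.511 with an estimated correlation), though after centring splicing factors went from 3 that rose and 37 that fell to 17 and 19, V-type ATPase genes from 2 and 11 to 6 and 8, and mitochondrial import genes from 2 and 14 to 2 and 8. The eif-stem, chaperonin and histone families were not called (adjusted p = 0.117, 0.188 and 0.638). With 10 splits of the 6 arrays no share can lie under 0.05; the real split called 9 families, the highest other 10, and 5 of 10 splits gave as many.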
